A study of Mus musculus with 66 samples.

How the data were processed

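Whole testes of the mouse were profiled on 66 oligonucleotide expression arrays. Testes from 11 ages were measured, at days 0, 3, 6, 8, 10, 14, 18, 20, 30, 35 and 56 after birth, with 2 numbered samples per day. Each numbered sample was run on 3 array types, here called A, B and C, which carry 12488, 12477 and 11934 probe sets, so that each type holds 22 arrays. The labels do not state whether the samples of a day were separate animals or pools.

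The deposited values are one signal intensity per probe set and array on a linear scale, which the authors scaled to a common target signal. The scaling was checked on the deposited values: after leaving out 2% of the probe sets at each end, the mean signal of every array lay between 125.0 and 125.1. The software that made the signals is not stated. Detection calls were not available, so the precision rests on the number of arrays and on the level of the signal. Between 46.0% and 63.1% of the probe sets of an array reached a signal of 50.

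Probe sets were named with the annotation deposited for the array types. Of 36899 probe sets, 198 were controls, 29131 named 1 gene, 724 named several genes and 6846 named none. Probe sets that named 1 gene were used for all gene counts, and 29044 of them were found under that gene in a reference table of mouse genes (assembly GRCm38.p6). Chromosomes were taken from that table by name, and no coordinates were used.

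Signals were analysed as log2(signal + 16). Probe sets with a signal of at least 50 on at least 2 of the 22 arrays of their type were kept, which left 26941. Each gene was represented by its probe set with the highest mean signal, and 13472 genes were tested. Each array type was fitted on its own in limma 3.58.1 under R 4.3.3, with lmFit on 11 day means and eBayes with a variance trend. The spread was shared by all days, which gives 11 residual degrees of freedom per probe set before moderation. All p values are two-sided, and were adjusted by the Benjamini-Hochberg method over all genes of the 3 array types within each comparison. A gene was called at an adjusted p under 0.05 with a change of at least 2-fold on the shifted scale. Changes are given as log2 change ± SE, and signals as mean ± SD of the 2 samples of a day (n = 2).

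The comparisons were a moderated F-test over all days, 6 windows (day 0 to 8, 8 to 14, 14 to 20, 20 to 35, 35 to 56 and 0 to 56), 10 steps between neighbouring days and 10 comparisons with day 0. The onset of a gene was the first day from which it was called higher than at day 0 at that day and at every later day. With 2 samples per day, Dixon's test for an outlying sample and a count of other splits of the samples, which need larger groups, were not run. Samples were compared by their correlations within and between days.

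There were 26 gene lists: gonocyte and undifferentiated spermatogonia, differentiating spermatogonia, early meiotic prophase, pachytene and diplotene spermatocyte, round spermatid, elongating and condensing spermatid, Sertoli cell, fetal and shared steroidogenic Leydig cell, adult Leydig cell, peritubular myoid and smooth muscle, macrophage, endothelium, erythroid, extracellular matrix, mitotic cell cycle, imprinted and fetal growth, cholesterol biosynthesis, testis-specific metabolic isozymes, somatic counterparts of these isozymes, retinoid metabolism and signalling, blood-testis barrier and junction, ciliary and flagellar axoneme, immediate-early response, epididymis, adipocyte and skeletal muscle. Some genes are in more than 1 list. Lists were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, on the arrays of the 3 types stacked by day and sample number, and adjusted over 150 tests of 25 lists in 6 windows. The epididymis list had 2 measured members and was not tested. The same test was run with the correlation estimated from the data, and members called were also counted after adjustment over the list alone. Genes on chromosome X were compared with autosomal genes in the same way, adjusted over the 6 windows, and their share of the onset classes was tested by Fisher's exact test.

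Named genes were chosen by rule: in each window the 8 largest rises and the 8 largest falls among called genes whose later samples all lay on one side of the earlier samples, without loci that have only a clone name; up to 4 members of each list with the largest called changes; and 40 genes chosen for their textbook roles in the testis, of which H1f6, Hbb-b1 and H19 were not measured. These comparisons, lists, thresholds and the naming rule were set before the data were examined. The Fisher's exact tests of X-linked shares and the bounds of the onset classes were not part of that plan.

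Alternatives set before the data were examined were pseudocounts of 1 and 64, a floor of 32 in place of a pseudocount, no signal filter, a filter of 125, quantile normalization, scaling of each array to the median of its type, all probe sets, the mean probe set of a gene, leaving out probe sets whose suffix marks shared or mixed sequence, the sample number as a block, no variance trend, a fit of only the arrays compared, no minimum fold, an estimated correlation, X-linked genes without germ cell list members, and leaving out each sample in turn. Alternatives added after the data were seen were days 0 and 20 from 1 sample each (leaving out sample 1 on type A and sample 2 on types B and C, those with the lower actin control signal), the sample number as a block at days 0 to 20 only, and an estimated correlation after exchanging the sample numbers of types B and C at days 0 to 20. A list of milk and mammary gland genes was also added after the data were seen.

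The procedure was tested on simulated data for the comparison of day 14 with day 20, in which 200 of 13472 genes were changed. It called 32% of genes changed 2-fold, 62% of those changed 3-fold, 84% of those changed 4-fold and 90% of those changed 8-fold. Of 141 genes called there, 7 had not been changed. The simulated noise was independent and had the same spread on all days. In the data the SD of the difference between the samples on type A was 0.4 at day 14 and 0.69 at day 20. The data also had far more called genes in this window (2124). These rates therefore need not hold for the data.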

Results

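The series follows gene expression in the mouse testis from birth to adulthood. This span takes in the first wave of spermatogenesis, in which spermatogonia differentiate, spermatocytes pass through meiosis and haploid spermatids form. It holds 2 numbered samples at each of 11 ages, and each number was taken as 1 RNA sample measured on 3 array types. The values are scaled array signals. Samples are named by their day and number, and the number of arrays limits the precision. Whole testes were used and every array was scaled to the same mean. A rise or fall is therefore relative to all signals of an array. It cannot be told apart from a change in the share of cells that express the gene. The correlation across probe sets between the samples of a day ran from 0.889 to 0.976 on array type A, from 0.804 to 0.95 on type B and from 0.78 to 0.941 on type C. It was lowest at day 0 on every type. At day 20 it was 0.896, 0.824 and 0.875 on types A, B and C. On type C it was also low at day 3 (0.792) and day 6 (0.873). At days 0 to 20 actin control probe sets were lower in sample 1 on type A and higher in sample 1 on types B and C.

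**Figure D1:**
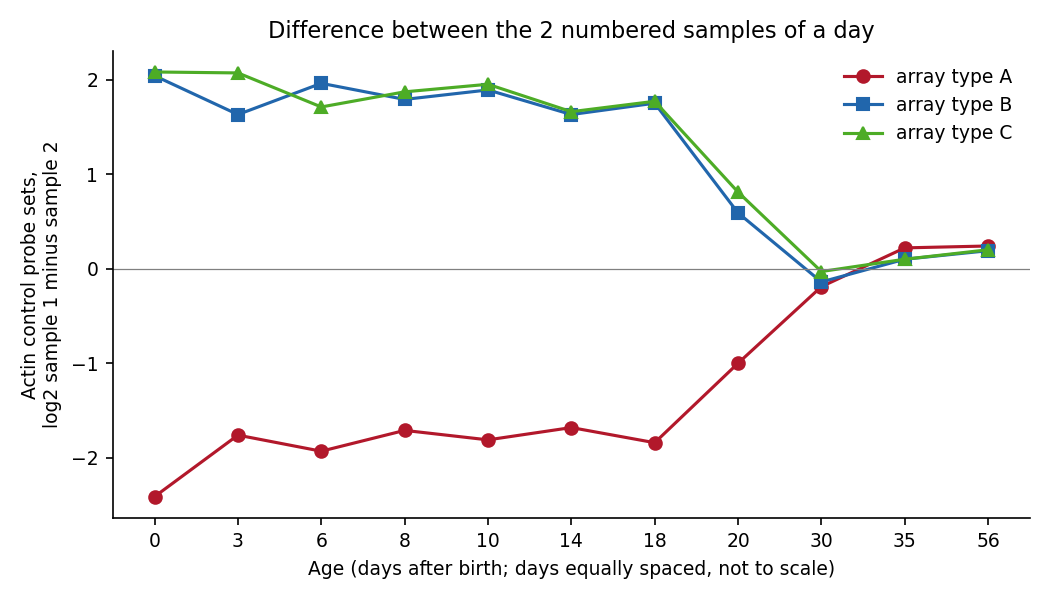
Mean log2 difference of the actin control probe sets between sample 1 and sample 2 of each day (sample 1 minus sample 2), by age in days and array type. At days 0 to 20 it lies between -2.41 and -1 on type A and between 0.59 and 2.08 on types B and C, and at days 30 to 56 between -0.19 and 0.24.

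More than 1 in 2 of the measured genes changed with age. The F-test over all days called 7264 of 13472 genes (53.9%). From day 0 to day 56, 4982 genes were called, 2138 higher and 2844 lower. The number of genes that differed from day 0 was 2942 at day 18, 4837 at day 30 and 4978 at day 35. Of the steps between neighbouring days, 3 held nearly all calls. They were day 10 to 14 with 95 genes (89 higher), day 14 to 18 with 694 (572 higher) and day 20 to 30 with 1004 (698 higher), the last of which spans 10 days. The step from day 20 to 30 called 619 genes without day 30 sample 1 and 614 without day 30 sample 2. With days 0 and 20 taken from 1 sample each, the step with the most calls was day 14 to 18, with 868 genes. Each of the other steps called between 0 and 4 genes with limma, while 303 to 1546 genes per step had an unadjusted p under 0.05. Where nothing changes, a share of 0.05 of the 13472 genes would have such a p. The counts for day 6 to 8 (455), day 8 to 10 (373) and day 30 to 35 (303) lie below that share. The count of 4, from day 0 to day 3, became 32 without day 0 sample 1, 10 without day 0 sample 2, 30 without day 3 sample 1 and 0 without day 3 sample 2. It lay between 0 and 2 when 1 sample of any later day other than day 8 was left out.

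The comparison of day 0 with day 8 covers the first differentiation of spermatogonia. Genes of germ cells that enter differentiation and meiosis rose. Stra8, the retinoic acid target needed for meiotic entry, rose from a signal of 8.4 ± 4.81 to 293 ± 37.1 (log2 change 3.67 ± 0.27, adjusted p = 2.12e-06). Dmrtb1, a regulator of the switch from mitosis to meiosis, rose by 2.88 ± 0.44, and the germ cell helicase gene Ddx4 by 2.06 ± 0.3. Uba1y, a Y-linked gene of spermatogonia, rose by 2.04 ± 0.2. Of the 17 measured genes of differentiating spermatogonia, 11 rose and 0 fell (13 rose when adjusted over the list alone), with a median log2 change of 1.87 (adjusted p = 9.37e-19). Of 21 genes of early meiotic prophase, 5 rose and 0 fell (7 rose when adjusted over the list alone, list adjusted p = 5.93e-07). Among them was Syce1, which encodes a protein of the synaptonemal complex (2.02 ± 0.23). Sycp1, of the same complex, rose by 2.76 ± 0.54, but was not called without day 0 sample 1 (adjusted p = 0.053), day 8 sample 1 (0.078) or day 8 sample 2 (0.0592), nor with a pseudocount of 64 (0.0562). Kit, the stem cell factor receptor, rose by 1.9 ± 0.34, but was not called without day 8 sample 2 (1.75, adjusted p = 0.0626) or with days 0 and 20 from 1 sample each (1.53, adjusted p = 0.051).

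Between days 0 and 8 genes of other testis cells moved both ways. Cldn11, the claudin of the Sertoli cell barrier, rose from 66.5 ± 11.4 to 606 ± 113 (2.91 ± 0.24, adjusted p = 4.49e-06). Crabp1, a retinoic acid binding protein that is counted in the list of differentiating spermatogonia, rose by 1.97 ± 0.29. Qpct, which encodes glutaminyl cyclase, had the largest rise of the window (3.91 ± 0.37). The chemokine gene Ccl17 had the largest fall (-3.89 ± 0.3), followed among named genes by Adcy2, an adenylyl cyclase (-3.32 ± 0.34), and Cspg4, a proteoglycan of pericytes (-2.9 ± 0.4). Cyp11a1, the first enzyme of steroid synthesis, fell from 1033 ± 400.0 to 191 ± 6.58 (-2.29 ± 0.3). The list of fetal and shared steroidogenic Leydig genes fell, with 2 of 19 lower and 0 higher (5 and 1 adjusted over the list alone, adjusted p = 0.000264, and adjusted p = 0.0886 with an estimated correlation and exchanged sample numbers). The extracellular matrix list fell, with 7 of 38 lower (8 adjusted over the list alone, adjusted p = 2.92e-10, and adjusted p = 0.0898 with an estimated correlation and exchanged sample numbers) and the microfibril gene Mfap2 at -2.02 ± 0.26. The imprinted and fetal growth list fell, with 5 of 24 lower and 0 higher (6 and 1 adjusted over the list alone, adjusted p = 0.000267, and adjusted p = 0.132 with an estimated correlation and exchanged sample numbers), among them the imprinted genes Mest (-1.96 ± 0.23) and Plagl1 (-1.45 ± 0.24). The endothelium list fell, with 2 of 16 lower (5 adjusted over the list alone, adjusted p = 1.51e-06). The Sertoli list had 5 of 38 genes higher and 4 lower (6 and 5 adjusted over the list alone) and was not called (adjusted p = 0.631). Krt8, a keratin in that list, changed by -2.58 ± 0.41.

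Scaling each array to the median of its type turned the balance of calls from day 0 to day 8 to 141 higher and 174 lower. The window from day 0 to day 8 called 351 genes in the main fit, 184 higher and 167 lower. It called 150 without day 8 sample 1 and 137 without day 8 sample 2. The junction list was called higher, with 2 of 24 genes higher (2 adjusted over the list alone, adjusted p = 0.026). It was not called with an estimated correlation (adjusted p = 0.196 with an estimated correlation), without day 0 sample 1 (0.118) without day 8 sample 1 (0.097) or with days 0 and 20 from 1 sample each (0.0779).

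From day 8 to day 14, when the first spermatocytes reach pachytene, 152 of the 191 called genes rose. Ldhc, the lactate dehydrogenase of germ cells, rose from 4 ± 1.13 to 638 ± 188 (5 ± 0.74, adjusted p = 0.000922). Ldhal6b, a related gene, rose by 5.29 ± 0.75, Fabp9, a fatty acid binding protein of the testis, by 4.47 ± 0.61 and Ybx2, an RNA-binding protein of germ cells, by 3.35 ± 0.48. Hspa2, a chaperone of meiotic cells, rose by 2.71 ± 0.29, and Spo11, which makes the DNA breaks that start recombination, by 2.2 ± 0.3. Gml had the largest rise (5.58 ± 0.47). Of 35 pachytene and diplotene genes 14 rose (18 adjusted over the list alone), with a median of 1.17 (adjusted p = 6.84e-25, and adjusted p = 0.00256 with an estimated correlation). Of 21 early meiotic genes 9 rose (12 adjusted over the list alone, adjusted p = 8.78e-17), including Msh4, a crossover protein (2.32 ± 0.37). Of 19 testis-specific isozymes 5 rose (6 adjusted over the list alone, adjusted p = 2.89e-07). They included Pdha2, the testis form of a pyruvate dehydrogenase subunit (2.81 ± 0.24), and Cox8c, a cytochrome oxidase subunit (4.31 ± 0.55). The axoneme list rose already in this window, with 6 of 38 higher (11 adjusted over the list alone, adjusted p = 1.9e-15) and the dynein chain gene Dnah8 at 2.5 ± 0.23. In these 4 lists 0 members fell.

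Imprinted genes fell between days 8 and 14, with 5 of 24 lower and 0 higher (6 lower when adjusted over the list alone, adjusted p = 3.41e-09) and the imprinted zinc finger gene Plagl1 at -2.28 ± 0.24. Postn, which encodes the matrix protein periostin, changed by -1.85 ± 0.23. In the extracellular matrix list 2 of 38 members were lower (3 adjusted over the list alone, adjusted p = 5.63e-07, and adjusted p = 0.107 with an estimated correlation). Tsx, an X-linked gene in the Sertoli list, rose by 2.83 ± 0.31. That list was not called, with 2 of 38 genes higher and 2 lower and the same numbers adjusted over the list alone (adjusted p = 0.787). The smooth muscle list was called lower with 0 of 16 members called and 0 adjusted over the list alone (median -0.38, adjusted p = 0.000682, and adjusted p = 0.0747 with an estimated correlation).

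The round spermatid list was called higher from day 8 to day 14, with 2 of 35 higher (5 adjusted over the list alone, median 0.08, adjusted p = 0.0369, and adjusted p = 0.16 with an estimated correlation). It was not called without day 8 sample 1 (adjusted p = 0.0531), day 8 sample 2 (0.0632), day 14 sample 1 (0.0526) or day 14 sample 2 (0.0548), nor with a pseudocount of 1 (0.0735) or a filter of 125 (0.079). With suffixed probe sets left out the median was -0.06 (adjusted p = 0.347). The macrophage list was called higher with 0 of 20 members called and 0 adjusted over the list alone (median 0.25, adjusted p = 0.0141, and adjusted p = 0.119 with an estimated correlation). It was not called without day 8 sample 2 (adjusted p = 0.141) or day 14 sample 1 (0.0867), nor with no filter (0.0809) or a filter of 125 (0.154). The window called 111 genes without day 8 sample 1, 116 without day 8 sample 2, 112 without day 14 sample 1 and 89 without day 14 sample 2.

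From day 14 to day 20, the stretch of late pachytene and the first meiotic divisions, spermatocyte and flagellar genes rose. Pgam2, a phosphoglycerate mutase of muscle and testis, rose from 2.45 ± 1.2 to 1530.0 ± 428 (6.36 ± 0.32, adjusted p = 5.07e-09). Tcp11, a gene of germ cells, rose by 4.36 ± 0.3, Cetn1, a centrin of the germ line, by 4.11 ± 0.29 and Insl6, of the insulin and relaxin family, by 4.03 ± 0.38. Ccna1, the meiotic A-type cyclin, rose from 5.7 ± 1.84 to 234 ± 12.3 (3.53 ± 0.46). Of 35 pachytene and diplotene genes 27 rose and 0 fell (27 and 1 adjusted over the list alone), with a median of 2.13 (adjusted p = 2.06e-19). Of 38 axoneme genes 25 rose (26 adjusted over the list alone, median 2.14, adjusted p = 4.13e-18). Among them were Dnali1, a dynein light intermediate chain (3.92 ± 0.55), and Drc1, of the dynein regulatory complex (3.36 ± 0.41). Of 19 isozyme genes 10 rose (10 adjusted over the list alone, adjusted p = 6.43e-07), including the glucose transporter gene Slc2a3 (3.74 ± 0.35) and Pgk2, the germ cell phosphoglycerate kinase (2.54 ± 0.36). In the round spermatid list 10 of 35 genes rose (10 adjusted over the list alone, adjusted p = 5.82e-06, and adjusted p = 0.0886 with an estimated correlation and exchanged sample numbers), such as Zpbp2, which encodes a zona pellucida binding protein (4.45 ± 0.36), and Acrbp, of the acrosome (3.28 ± 0.34). In the elongating spermatid list 9 of 34 rose (10 adjusted over the list alone, adjusted p = 3.06e-05, adjusted p = 0.044 with an estimated correlation, and adjusted p = 0.176 with exchanged sample numbers too), such as Spag16, of the central pair of the flagellum (3 ± 0.49).

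Between days 14 and 20 the whole-testis signals of single genes of spermatogonia, the matrix and Sertoli cells fell. Whether expression per cell or the share of these cells changed was not tested. Stra8 fell from 323 ± 40.9 to 84.8 ± 23.7 (-1.77 ± 0.27), and Usp26, an X-linked gene of spermatogonia, changed by -1.55 ± 0.28. In the list of differentiating spermatogonia 6 of 17 genes fell and 1, Dmrtb1 (3.11 ± 0.44), rose, with the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.115). The collagen genes Col5a1 (-2.27 ± 0.32), Col5a2 (-2.06 ± 0.29) and Col1a2 (-1.7 ± 0.25) fell. Of 38 matrix genes 16 were lower (18 adjusted over the list alone, adjusted p = 2.52e-09, and adjusted p = 0.054 with an estimated correlation). Kitl, the stem cell factor made by Sertoli cells, fell from 484 ± 20.8 to 97.4 ± 97.7 (-2.47 ± 0.47). Of 38 Sertoli genes 8 were lower and 0 higher (9 and 1 adjusted over the list alone, adjusted p = 0.00334, and adjusted p = 0.0741 with an estimated correlation). Of 24 junction genes 9 were lower, among them the occludin gene Ocln (-1.96 ± 0.28), and 1 higher, Nectin3 (1.95 ± 0.4), with the same numbers adjusted over the list alone. The junction list was called lower (adjusted p = 0.000934, and adjusted p = 0.0741 with an estimated correlation). Imprinted and fetal growth genes fell, with 8 of 24 lower (9 adjusted over the list alone, adjusted p = 0.000378, and adjusted p = 0.141 with an estimated correlation and exchanged sample numbers), including Peg3 (-1.97 ± 0.35), Igf1 (-1.85 ± 0.32) and Dlk1 (-1.67 ± 0.34). Ube2d1, a ubiquitin-conjugating enzyme, fell from 468 ± 133 to 73.0 ± 80.3 and Dek, a chromatin protein, from 725 ± 35.1 to 152 ± 169. For these genes, as for Kitl, the SD at day 20 exceeded the mean.

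The window from day 14 to day 20 called 2124 genes, 998 higher and 1126 lower. It called 1405 without day 14 sample 2, and with days 0 and 20 taken from 1 sample each it called 883 higher and 753 lower. Scaling each array to the median of its type moved the median change of all genes from -0.11 to 0.09 and gave 1308 higher and 647 lower. Each called list kept the sign of its median under this scaling, with -0.72 for the matrix list, -0.6 for the imprinted list, -0.55 for the junction list and -0.28 for the Sertoli list. The immediate-early list was called lower, with 2 of 17 genes lower and 2 adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.13 with an estimated correlation). The call was lost without day 20 sample 1 (0.0856), with a filter of 125 (0.079) and with quantile normalization (0.0693). The smooth muscle list was called lower, with 2 of 16 genes lower and 2 adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.196 with an estimated correlation). The call was lost without day 14 sample 1 (0.0744), without day 20 sample 2 (0.226) or with each array scaled to the median of its type (0.0756).

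**Figure D2:**
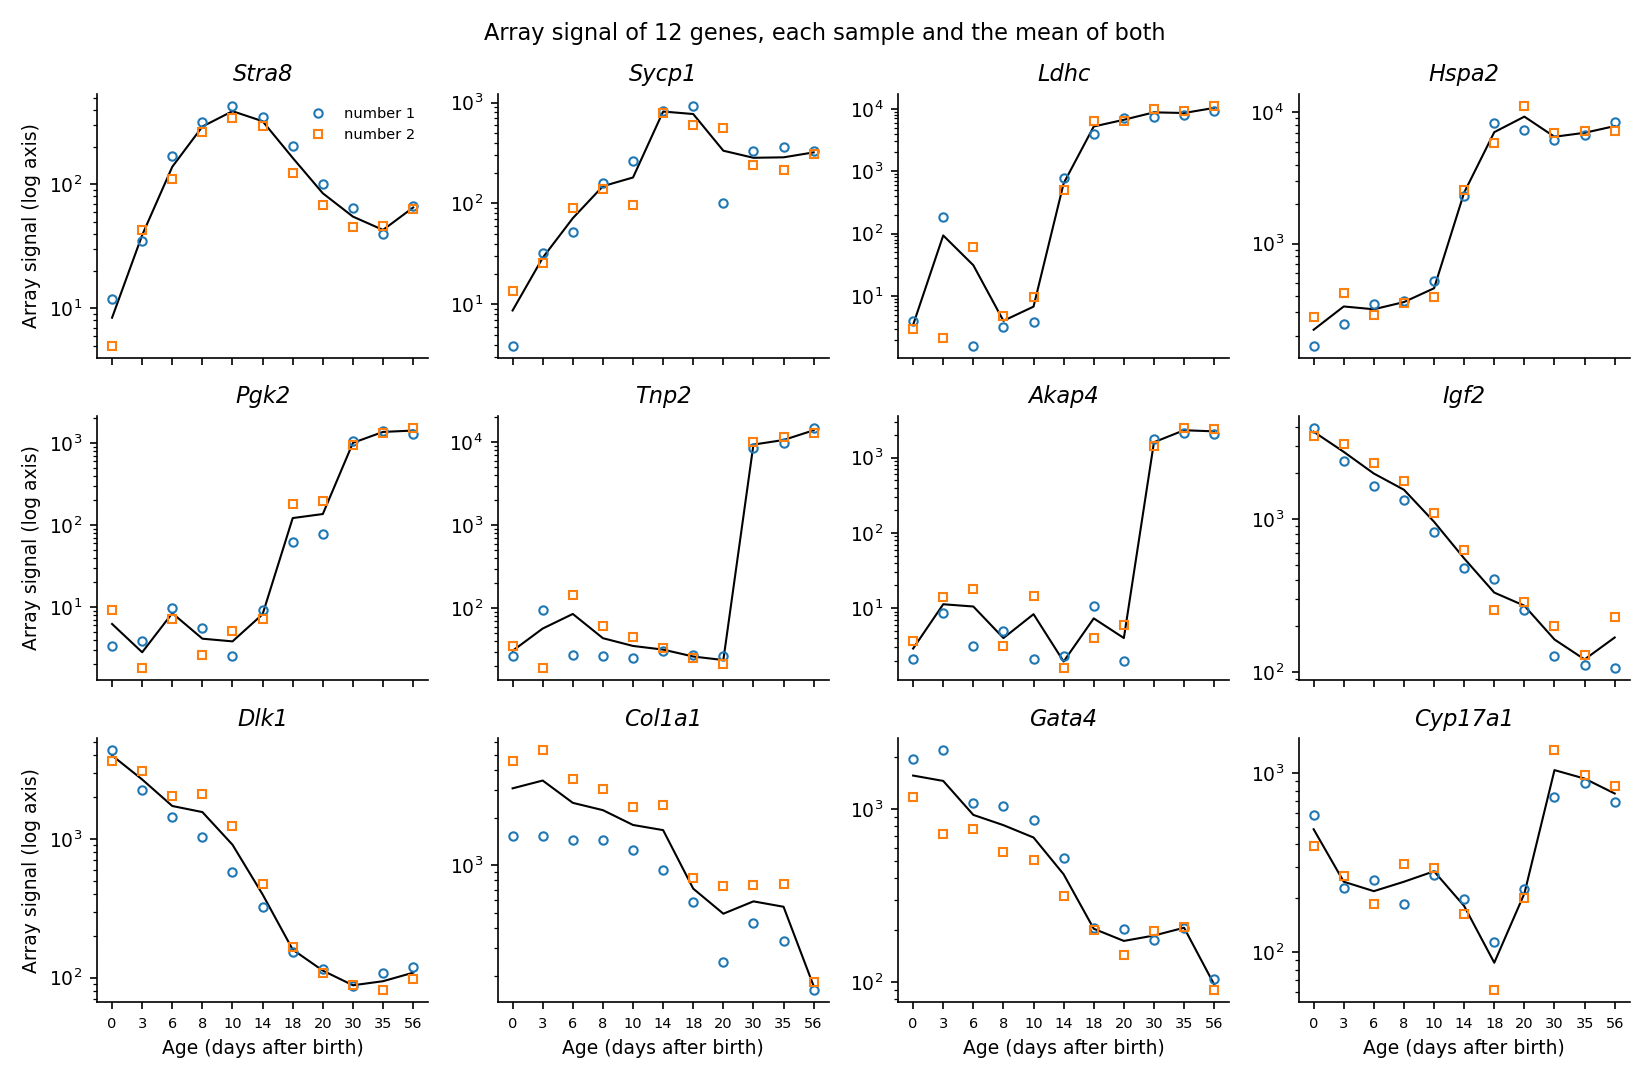
Array signal (log axis) of 12 genes against age in days, equally spaced, for both samples of each day, with a line through their mean. Stra8 has its highest mean at day 10, Tnp2 and Akap4 are high from day 30 on, and Igf2, Dlk1 and Col1a1 are lower at day 56 than at day 0.

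From day 20 to day 35, when spermatids form and elongate, the spermatid lists rose. Prm1, the protamine that packs sperm DNA, rose from 9.15 ± 3.32 to 12220.0 ± 291 (8.93 ± 1.22, adjusted p = 4.98e-05), and the transition protein genes Tnp2 and Tnp1 by 8.07 ± 0.5 and 4.7 ± 0.31. Akap4, the main protein of the fibrous sheath, rose from 4 ± 2.83 to 2313 ± 248 (6.87 ± 0.29). Smcp, of the mitochondrial capsule, rose by 7.1 ± 0.47, and Odf1, of the outer dense fibres, by 6.03 ± 0.28. Among round spermatid genes Actrt2 rose by 6.93 ± 0.29, the kinase genes Tssk3 and Tssk6 by 6.7 ± 0.28 and 5.97 ± 0.59, and the acrosomal gene Acrv1 by 4.83 ± 0.31. Of 35 round spermatid genes 22 rose and 0 fell (24 rose when adjusted over the list alone), with a median of 3.36 (adjusted p = 1.99e-31). Of 34 elongating spermatid genes 21 rose and 0 fell (21 rose when adjusted over the list alone), with a median of 2.37 (adjusted p = 5.16e-26). Iqcf3 (8.26 ± 0.3), Lelp1 (7.25 ± 0.36) and Spz1, a transcription factor gene of the testis (7.2 ± 0.32), were among the largest rises.

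Enzymes and flagellar genes of the spermatid rose over the same days 20 to 35. Gapdhs, the sperm form of glyceraldehyde phosphate dehydrogenase, rose by 6.65 ± 0.33, the aldolase gene Aldoart2 by 3.67 ± 0.23 and Pgk2 by 3.3 ± 0.36. Of 19 isozyme genes 5 rose (5 adjusted over the list alone, adjusted p = 0.000262). The tektin genes Tekt2 and Tekt4 rose by 2.75 ± 0.35 and 2.16 ± 0.3 and the ciliary transcription factor gene Foxj1 by 2.14 ± 0.36, and 8 of 38 axoneme genes rose (8 adjusted over the list alone, adjusted p = 0.00334, and adjusted p = 0.4 with an estimated correlation and exchanged sample numbers). In the pachytene list 10 of 35 genes rose (12 adjusted over the list alone, adjusted p = 7.64e-06, and adjusted p = 0.126 with an estimated correlation), with the heat shock genes Hspa1l at 4.92 ± 0.25 and Dnaja4 at 6.61 ± 0.5. Cyp17a1, an enzyme of androgen synthesis, rose from 213 ± 16.5 to 933 ± 70.9 (2.05 ± 0.31). The adult Leydig list was not called, with 2 of 16 higher (3 adjusted over the list alone, adjusted p = 0.227). In the adipocyte list 2 of 7 genes rose, Lipe, the hormone-sensitive lipase that the testis also makes (3.2 ± 0.31), and Adipoq (1.77 ± 0.3), and 3 when adjusted over the list alone. The list was called (adjusted p = 0.00168, and adjusted p = 0.147 with an estimated correlation).

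Falls between days 20 and 35 included globin and germ cell genes. The globin genes Hbb-b2 and Hba-a1 changed by -3.12 ± 0.41 and -2.36 ± 0.37, from day 20 signals of 1731 ± 1010.0 and 3570.0 ± 2020.0. The erythroid list was not called, with 2 of 7 lower and 2 adjusted over the list alone (adjusted p = 0.512). Tex101, a surface protein of germ cells, changed by -1.91 ± 0.27, Mov10l1, a helicase of the piRNA pathway, by -1.39 ± 0.2 and the claudin gene Cldn12 by -2.07 ± 0.34. The window called 1395 genes, 816 higher and 579 lower. It called 884 without day 35 sample 1 and 927 without day 35 sample 2.

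Between day 35 and day 56 limma called 0 of 13472 genes, with 1235 at an unadjusted p under 0.05, and 0 of 25 lists. Akap4 had signals of 2313 ± 248 and 2235 ± 211 at these days, and Tnp2 of 10680.0 ± 1300.0 and 13990.0 ± 1380.0. Alternative fits called genes here: 19 with the sample number as a block, 50 with that block at days 0 to 20 only and 45 with only the arrays of these days. Without day 56 sample 2, 15 genes were called, all lower. Without day 0 sample 1, day 18 sample 1, day 18 sample 2 or day 35 sample 1, the count was 2, 3, 3 and 1.

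Across the whole span from day 0 to day 56, the lists of meiotic and later germ cells rose. Ldhc rose from 3.45 ± 0.636 to 10330.0 ± 1350.0 (9.05 ± 0.74). Iqcf3 rose by 9.26 ± 0.3, Fam229a by 9.11 ± 0.62, Pdcl2 by 8.33 ± 0.57, Tnp2 by 8.23 ± 0.5 and Spata19 by 8.15 ± 0.49. Meig1, needed for spermiogenesis, rose by 7.08 ± 0.44, Crisp2, a sperm protein, by 7.34 ± 0.55 and Hmgb4, a chromatin protein of the germ line, by 7.47 ± 0.3. In the pachytene list 33 of 35 genes were higher (adjusted p = 6.06e-25), in the round spermatid list 31 of 35 with 1 lower (adjusted p = 1.71e-23), and in the elongating spermatid list 29 of 34 (adjusted p = 8.43e-20). In the axoneme list 30 of 38 were higher (adjusted p = 3.43e-17), in the isozyme list 13 of 19 with 2 lower (adjusted p = 6.95e-10), and in the early meiotic list 13 of 21 (adjusted p = 6.43e-07). The numbers adjusted over the list alone were the same in these 6 lists.

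From day 0 to day 56 genes of fetal growth and of the matrix fell. Plagl1 fell from 10530.0 ± 969 to 125 ± 12.3 (-6.22 ± 0.24, adjusted p = 4.53e-12), Igf2, the fetal growth factor, from 3710.0 ± 310.0 to 168 ± 87.5 (-4.42 ± 0.32) and Dlk1 from 4001 ± 515 to 109 ± 15.1 (-5.01 ± 0.34). Of 24 imprinted and fetal growth genes 16 were lower and 0 higher, the same as adjusted over the list alone (median -1.9, adjusted p = 6.05e-06, and adjusted p = 0.0602 with an estimated correlation and exchanged sample numbers). Col5a1 changed by -6.18 ± 0.32 and Bgn, the proteoglycan biglycan, by -4.71 ± 0.51, and 36 of 38 matrix genes were lower, also 36 adjusted over the list alone (median -2.58, adjusted p = 6.85e-14). Gata4, a transcription factor of somatic testis cells, changed by -3.77 ± 0.43 and Hsd17b1 by -4.18 ± 0.34. Of 38 Sertoli genes 21 were lower and 4 higher, the same as adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.119 with an estimated correlation). Tpm1, a tropomyosin, changed by -3.08 ± 0.21, while Actg2, the smooth muscle gamma actin, rose by 2.83 ± 0.24. Of 16 smooth muscle genes 9 were lower and 1 higher, the same as adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.163 with an estimated correlation). Scaling to the median moved the median change of all genes from -0.21 to -0.04 and gave 2436 genes higher and 2352 lower.

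The endothelium list was called lower at day 56 than at day 0, with 8 of 16 lower and 1 higher (9 and 1 adjusted over the list alone, adjusted p = 0.0422, and adjusted p = 0.13 with an estimated correlation). It was not called without day 0 sample 2 (adjusted p = 0.0648), day 20 sample 1 (0.0507) or day 56 sample 2 (0.0684). Nor was it with a pseudocount of 1 (0.0509), a filter of 125 (0.1), quantile normalization (0.0507), suffixed probe sets left out (0.0695) or days 0 and 20 from 1 sample each (0.125). Cdh5, the cadherin of endothelium, changed by -3.64 ± 0.29. The junction list was called lower, with 11 of 24 lower and 3 higher, the same as adjusted over the list alone (adjusted p = 0.0376, and adjusted p = 0.227 with an estimated correlation). It was not called without day 0 sample 2 (adjusted p = 0.0544) or day 56 sample 2 (0.0701), nor with a filter of 125 (0.06), suffixed probe sets left out (0.102) or days 0 and 20 from 1 sample each (0.0693).

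The other lists were not called from day 0 to day 56, and their numbers were the same adjusted over the list alone. Of 17 genes of differentiating spermatogonia 5 were higher and 2 lower (adjusted p = 0.106). Of 16 genes of gonocytes and undifferentiated spermatogonia 4 were lower and 0 higher (adjusted p = 0.804), and of 45 mitotic cell cycle genes 12 and 7 (adjusted p = 0.206), with the proliferation marker Mki67 at -2.08 ± 0.32. Of 14 somatic counterparts of the isozymes 9 were lower and 2 higher (adjusted p = 0.0591), of 18 retinoid genes 8 and 3 (adjusted p = 0.541) and of 20 cholesterol biosynthesis genes 4 and 2 (adjusted p = 0.512). Of 7 skeletal muscle genes 0 were called (adjusted p = 0.787), and the epididymis list had 2 measured members and no test. The Leydig, macrophage, erythroid, immediate-early and adipocyte lists had adjusted p between 0.071 and 0.983. Fshr, the follicle-stimulating hormone receptor of Sertoli cells (208 ± 19 and 159 ± 17.5), Insl3 of Leydig cells (42.6 ± 19.1 and 43.9 ± 8.56), Clu (1951 ± 194 and 1468 ± 46.4) and the germ cell genes Dazl (191 ± 171 and 325 ± 25.7) and Sycp3 (48.3 ± 12.6 and 52.2 ± 50.1) were not called, with adjusted p of 0.0998, 0.895, 0.195, 0.364 and 0.884. Over all days the mean signal ran from 37.4 to 62.6 for Insl3 and from 10.1 to 64.3 for Sycp3. These lie near the filter of 50, so they cannot show whether either gene changed.

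**Figure D3:**
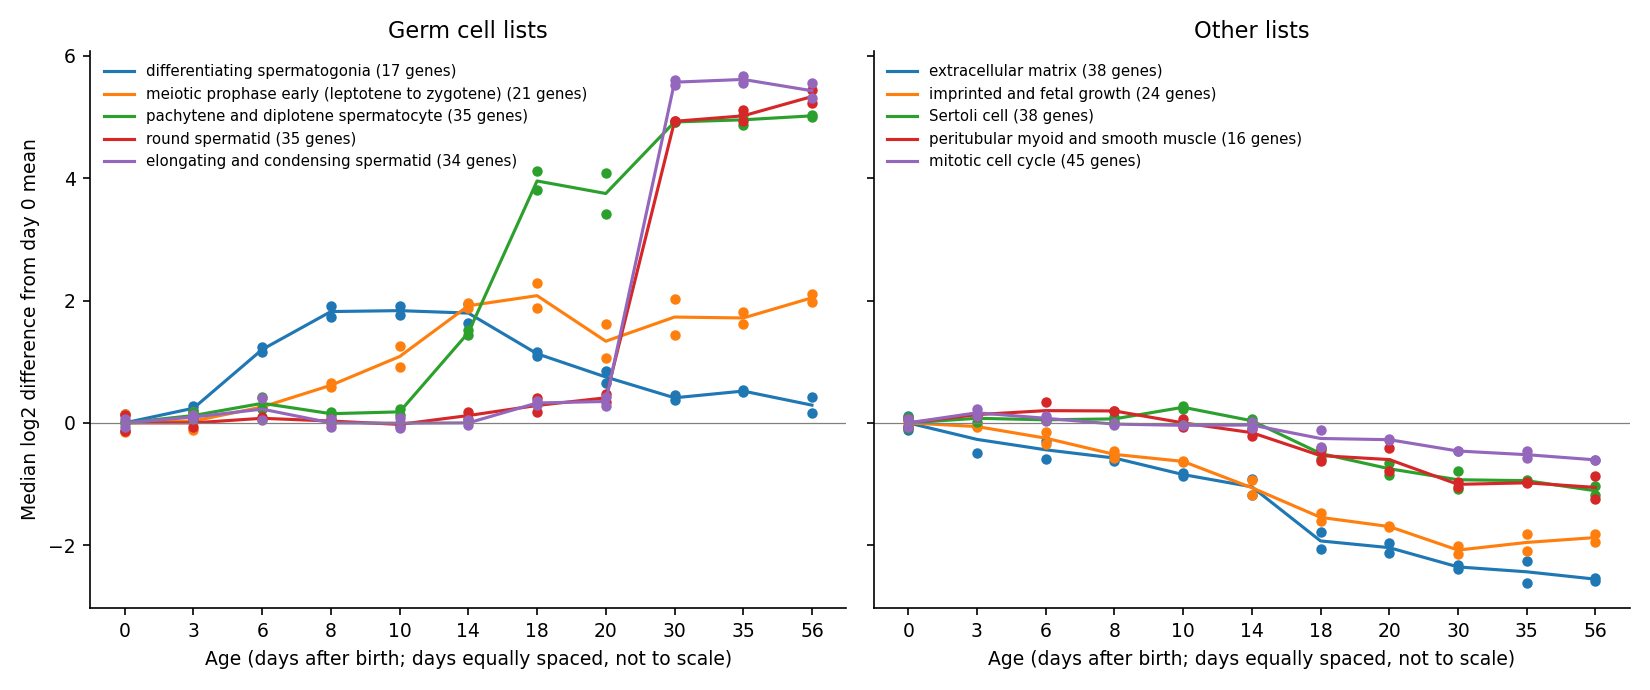
Median log2 difference of each list from its day 0 mean against age in days, equally spaced, with a point per sample and a line through the mean, for germ cell lists (left) and other lists (right). Both spermatid lists are highest from day 30 on, and the matrix and imprinted lists are lower at day 56 than at day 0.

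The onset of each gene gave the order of the germ cell lists. Stra8 and Ddx4 had their onset at day 6, Sycp1 at day 8, Hspa2 at day 10, Ldhc and Spo11 at day 14, and Pgk2 and Ccna1 at day 18. Prm1, Prm2, Tnp1, Tnp2, Akap4, Odf1 and Acrv1 had theirs at day 30. The median onset was day 8 for the 5 genes of differentiating spermatogonia that had one, and day 14 for 13 early meiotic genes and for 33 pachytene genes. It was day 18 for 30 axoneme genes and day 30 for 31 round and 29 elongating spermatid genes. In the elongating list 20 of these began at day 30. Across all genes, 261 had their onset at day 14, 633 at day 18, 139 at day 20 and 651 at day 30. The 2 samples of day 18 differed along the change from day 14 to day 20. The correlation of their difference, lower minus higher actin signal, with that change was -0.58 on type A. This limits how exactly onsets near day 18 are placed.

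Genes on chromosome X fell against autosomal genes between days 14 and 20, when spermatocytes, whose sex chromosomes are silenced, become abundant. The median of the 413 measured X-linked genes changed by -0.69 and that of the 13000 autosomal genes by -0.09, a difference of -0.61 (adjusted p = 2.58e-12). Of the X-linked genes 118 were called lower (28.6%, against 7.7% of autosomal genes) and 3 higher (0.7% against 7.6%). The X median lay below that of every autosome, which ran from -0.2 to 0.01. From day 0 to day 56 the difference was -0.71 (adjusted p = 1.97e-05). In that window 174 X-linked genes were lower (42.1%, against 20.5% of autosomal genes) and 38 higher (9.2% against 16.1%). Both calls held with an estimated correlation (adjusted p = 5.33e-07 and 2.96e-05). After the sample numbers of types B and C were exchanged at days 0 to 20, neither was called (adjusted p = 0.0978 and adjusted p = 0.318 with an estimated correlation). The differences in the other windows were 0.03, -0.12, -0.09 and 0.04 and were not called (adjusted p of 0.387, 0.0728, 0.387 and 0.387). From day 0 to day 8, however, 27 X-linked genes were called higher (6.5%, against 1.2% of autosomal genes). In that window 9 were called lower (2.2% against 1.2%). These shares were not compared by a test.

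X-linked genes were unevenly spread over the onset classes, in tests that were not set beforehand. They made up 10 of 65 genes with an onset at days 3 to 8 (15.4%, against 3.1% of measured genes, Fisher's exact test, adjusted p = 5.42e-05). Onsets were computed in the main fit alone. The calls against day 0 at days 3, 6 and 8, on which this class of genes rests, moved strongly when 1 sample was left out. Taf9b, Esx1 and Fmr1nb, named after their values were seen, were among the 10 X-linked genes. Of 1083 genes with an onset at days 10 to 20, 4 were X-linked (0.4%, Fisher's exact test, adjusted p = 3.25e-10), namely Tsx, Tsga8, Cypt3 and 1810030O07Rik, also named after their values were seen. At day 30 the share was 2.8% (18 of 645, including Akap4, Fisher's exact test, adjusted p = 0.815). At days 35 and 56 it was 1.8% (6 of 335, Fisher's exact test, adjusted p = 0.267).

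**Figure D4:**
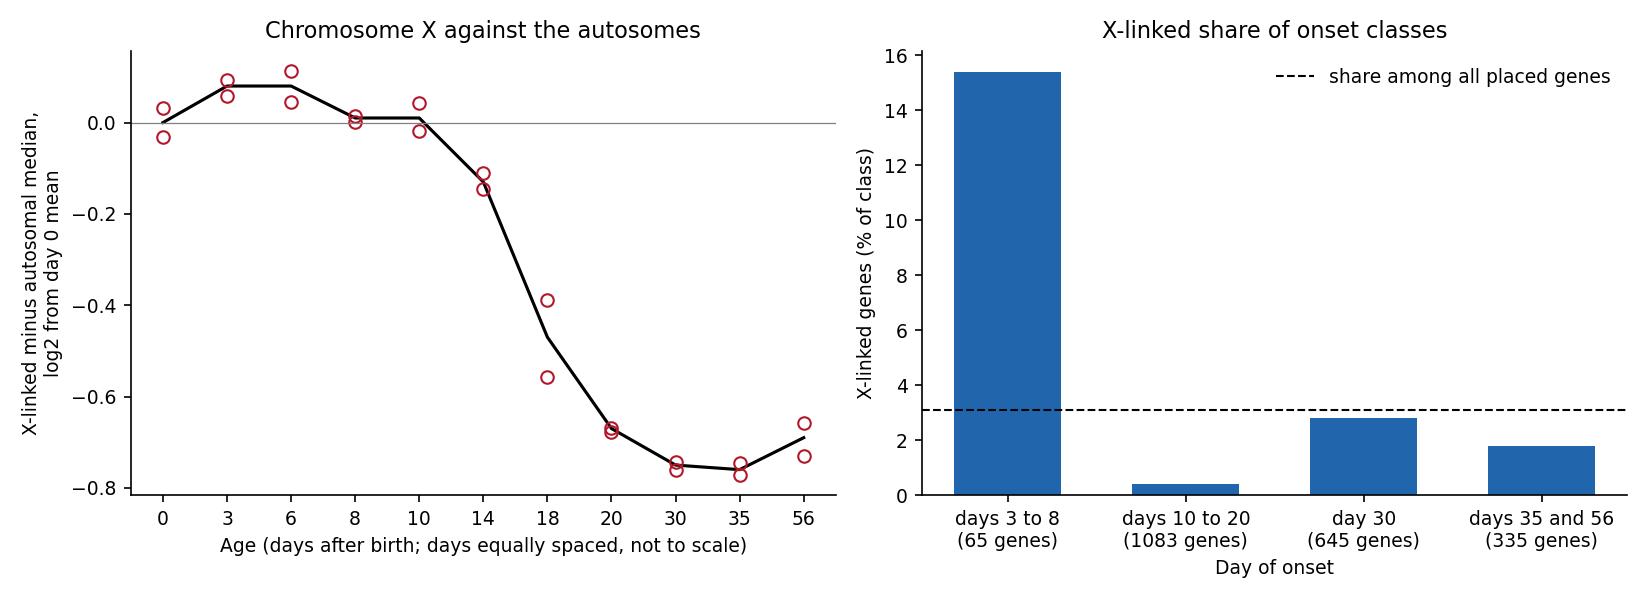
Median log2 difference from the day 0 mean of X-linked minus autosomal genes for each sample against age in days, equally spaced (left, with a line through the mean), and X-linked share in percent of the genes of each onset class (right, with a dashed line at the share among measured genes). The mean difference is 0.01 at day 10, -0.47 at day 18 and -0.67 at day 20.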

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

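Of the tests in this part, those of exchanged sample numbers and of RNA shortened from the 5' end were chosen after the result was seen. The actin control probe sets of the 2 numbered samples differed in opposite directions between array types. The log2 difference, sample 1 minus sample 2, averaged -1.77 on type A, 1.66 on type B and 1.74 on type C over days 0 to 20, with sample 1 lower on 8 of 8 days on type A and higher on 8 of 8 days on types B and C. It drew attention because every day moved one way on type A and the opposite way on types B and C, and the difference between the array types was not tested. On the 3 later days the differences lay between -0.19 and 0.24. Sample differences over the whole array also correlated between days. On types A, B and C the correlation exceeded 0.1 in 26, 26 and 23 of 28 pairs of days 0 to 20. Over all 55 pairs the counts were 28, 34 and 23. The main fit had no block for sample number. Comparisons of days 0 to 20 with the 3 later days span days with and without the actin difference. With that block, 514 of 517 values of named genes kept their direction and side of the threshold, and 505 with it at days 0 to 20 only.

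The values argue against RNA shortened from the 5' end in the sample with the lower actin signal. The 3' to 5' signal ratio of actin and Gapdh controls was not raised there (median log2 difference -0.21) and was at least 1.5-fold higher in 1 of 48 pairs. It was above that of the other sample in 9 of 48 pairs, and for Gapdh in 3 of 24 (median -0.32). The ratio thus tended to be higher in the sample with the higher actin signal, and shortening in that sample was not tested. A candidate explanation is that the sample numbers are exchanged between type A and types B and C at days 0 to 20. Across genes measured on both types, the difference between the samples of a day correlated at a median of -0.21 between types A and B, below 0 on 8 of 8 days, and above 0 on 8 of 8 days between types B and C, though genes are not independent replicates. A later stage of development in 1 sample of each day stays open, because the correlation with the change from the day before to the day after reached 0.1 on 1 of 8 days on type A, with 2 days below -0.1. For day 0, 1 of these 2, no earlier day exists and the change from day 3 to day 6 was used. No other biological explanation was tested, and neither explanation says why the actin signal itself differed.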

How the results depend on the processing

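Taking days 0 and 20 from 1 sample each, blocking by sample number at days 0 to 20 only, and exchanging sample numbers with an estimated correlation were chosen after the data were seen. Named genes were followed with pseudocounts of 1 and 64, quantile normalization, median scaling, both block settings, days 0 and 20 from 1 sample each, and without each sample in turn. They were not followed under the other alternatives, and other called genes were not followed one by one. No named gene that was called changed sign where it was followed. No called X minus autosomal difference changed sign under the alternatives in which it was tested. No called list changed the direction of its test there, although the median of the round spermatid list from day 8 to day 14 went from 0.08 to -0.06 with suffixed probe sets left out. Results that were not called did, such as the X minus autosomal difference from day 0 to day 8, and median scaling turned the balance of calls from day 14 to day 20 from 998 higher and 1126 lower to 1308 and 647. Of the values of named genes under alternatives set beforehand, 2436 of 2585 kept their direction and side of the threshold and 118 lost the call, and of those without 1 sample 10916 of 11374 kept both. From day 35 to day 56, where 0 genes were called, a pseudocount of 64 gave 10, a floor of 32 gave 12, no filter 5, quantile normalization 1, median scaling 2, every probe set 3, no variance trend 4, the sample number as a block 19, the block at days 0 to 20 only 50 and the fit of only the arrays compared 45. That fit uses fewer samples and takes the spread from the days compared alone. It called 4 genes from day 0 to day 8, 548 from day 14 to day 20, 566 from day 20 to day 35 and at most 459 in a step. On type A the SD of the log2 difference between the samples was 0.71 at day 0 and 0.69 at day 20. It was 0.36 at day 35 and 0.45 at day 56. The spread shared by all days in the main fit does not follow such differences between days. Counting every probe set, by construction a larger number of tests, called 11612 in the F-test and 8042 from day 0 to day 56, where 91 called genes had a probe set called in the opposite direction, as had 6 from day 14 to day 20 and 1 from day 20 to day 35, with no named gene among them. With days 0 and 20 from 1 sample each, 304 genes were called from day 8 to day 14, and the X minus autosomal difference from day 0 to day 8 was -0.06. Of 45 list calls, 29 held with an estimated correlation and 21 after the numbers were also exchanged. Calls that held could have a far larger adjusted p in camera with the estimated correlation. For the pachytene list from day 0 to day 56 it was 0.00256 against 6.06e-25. For the elongating spermatid list it was 0.000671 against 8.43e-20. With the exchange, 0 windows were called for chromosome X, with differences of -0.61 (day 14 to 20) and -0.71 (day 0 to 56) that no longer passed. The difference from day 8 to day 14 passed with an estimated correlation (-0.12) and with suffixed probe sets left out (-0.14), and that from day 35 to day 56 was 0 with the floor. For all these changes other than those of more tests, the cause was not tested. Without 1 sample in turn, the lone sample of a day being assumed to vary like the others, the ranges were 6855 to 7623 genes in the F-test, 137 to 436 from day 0 to day 8, 89 to 243 from day 8 to day 14, 1405 to 2252 from day 14 to day 20, 884 to 1597 from day 20 to day 35, 0 to 15 from day 35 to day 56, 4577 to 5031 from day 0 to day 56, 614 to 1277 in the step with the most and 42 to 48 lists. The X minus autosomal differences ranged from -0.02 to 0.03, from -0.62 to -0.59 (day 14 to 20) and from -0.73 to -0.65 (day 0 to 56). Signal over background limits genes near the filter of 50.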

Other observations

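All tests in this part were set before the result they measure was seen, although the patterns themselves had been noticed first and the samples left out at day 20 were chosen after the data were seen. Milk protein genes stood far above the other arrays on the type A array of day 6 sample 1, where Wap had a signal of 1264.4 against 7.2 in sample 2 and Csn1s1 849.7 against 3.8. For all 6 genes raised at least 4-fold there, the highest signal on other days was in day 56 sample 1. For Wap it was 54.1 (15 in day 56 sample 2) and for Csn1s1 77.9 (38.7). Of the listed milk and mammary genes not yet looked at, 17 were tested, and their median difference between these arrays was 0.14 (log2), at percentile 97.2 of random lists matched on signal, with 3 genes at least 4-fold higher. Other milk genes were raised little or not at all, among them Lalba (10.4 against 6.1, and up to 27.7 on other days), Btn1a1, Ltf and Xdh, so the list did not move as a whole. RNA of lactating mammary gland or milk in that sample is a candidate source, and no biological explanation was tested. Whether the same RNA was run on array types B and C cannot be told apart from its absence there. The largest difference between the day 6 arrays was 2.01-fold on those types, below the 4-fold set as a bound beforehand, but that bound was wrong: of 6 genes raised at least 4-fold on type A, 1, Csn1s2a, is carried on them, with signals of 28 and 39.2 that lie under the filter of 50.

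Transcripts of spermatids also appeared on 1 of the type A arrays of day 3 and of day 6, days at which the testis holds no spermatids. Prm1 had signals of 540.1 in sample 1 and 5.5 in sample 2 at day 3, and of 18 and 759 at day 6. Of 23 other probe sets that are high at day 56 and low at days 8 and 10, 69.6% were higher in sample 1 at day 3 and 95.7% in sample 2 at day 6. Prm1 also had signals of 128.6 and 98.3 in samples 1 and 2 at day 0. They were 4.3 and 98.6 at day 8, 62.5 and 87.3 at day 10, and 11.5 and 6.8 at day 20. Day 0 is therefore not free of Prm1 signal. The share at day 0 was 73.9% in sample 2 on type A and 71.4% in sample 2 on type C, so shares near 70% are not distinct from that day. The share of 69.6% at day 3 falls short of the 90% set beforehand for RNA of a testis with spermatids mixed into these arrays. This explanation therefore stays open. Mixing before the RNA was divided over the array types stays open too, since neither bound set beforehand was met on types B and C. At day 3, 72% of such probe sets on type B and 77.6% on type C were higher in sample 2, and at day 6, 68% and 77.6% were higher in sample 1. Each share is below the 80% set for mixing, and 3 of the 4 lie outside the range of 30% to 70% set against it. The direction is opposite to that on type A at both days, as it is for the actin controls.

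The fall of X-linked genes between days 14 and 20 was tested against 2 technical explanations. Against the signal level of X-linked genes at day 14, the X median of -0.69 lay at percentile 0 of 10000 autosomal lists matched on that signal, whose medians ran from -0.24 to 0.05. The other explanation was the day 20 samples that stand apart, taken as those with the lower actin control signal on their array type. No other measure picked them out. Without them and those of day 0, the difference from autosomal genes was -0.66, and with them it was -0.61. Without day 20 sample 1 on all types it was -0.62, and without day 20 sample 2 it was -0.59. These values argue against both explanations. Silencing of the sex chromosomes in spermatocytes and a change in the share of cell types stay open, and neither was tested.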
